A study of Homo sapiens with 4 samples.

How the data were processed

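RNA from HCT116 cells was extracted with RNeasy columns and labelled as biotinylated cRNA using Ambion MessageAmp reagents, per the labels' protocols. The deposited scanner table holds, for each of 4 arrays and 47224 probes, a bead intensity on a linear scale with no normalisation applied, per the file headers. It also gives a detection p-value, the standard error over beads and the number of beads, per the file headers. The authors' processed series values were taken as log2, from their size against the scanner intensities. Each column ranks the probes as the scanner column of the same array does (Spearman 1 in all 4), and the column medians were 6.257, 6.256, 6.256 and 6.255. Their close medians point to normalisation between arrays, of a kind that stays unknown. The submitters' processing notes name lumi, with no version, and the background step they used is not given in the sources used here.

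Groups came from the sample titles, 2 control and 2 circ-MDM2 siRNA arrays. The labels say the duplicates were biological. The labels call the knockdown stable and also say that siRNAs made it, so whether it was transient or stable stays unknown. How the siRNAs were delivered and for how long is not given in the sources used here. The replicate numbers were not taken to pair the arrays. No slide or scan identity was given, so batch could not be examined. The median probe was read from 22 beads on each array, with a bead standard error of 3.08% to 3.25% of the intensity. The highest intensity, 7019.5, gave no sign of saturation. Between 34.4% and 38.1% of probes were detected per array, so dim genes such as MDM2 are poorly resolved. The arrays of a group correlated at 0.995 (controls) and 0.991 (knockdown), and arrays of different groups at 0.976 to 0.982, across probes kept. The SD of the difference between duplicates was 0.19 for controls and 0.26 for knockdown arrays.

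The main values were computed with neqc in limma 3.58.1 (R 4.3.3, statmod 1.5.0), which corrects background from the detection p-values, adds an offset of 16, normalises by quantiles and takes log2. Probes with a detection p under 0.05 on at least 2 of the 4 arrays were kept, 17451 in all, after leaving out 1 control row. Quantile normalisation gives every array the same distribution, so a change in total RNA or of most genes in 1 direction would be hidden, and the offset shrinks the fold changes of dim probes. The probe of the highest mean stood for its gene, which left 13548 genes, 617 of them probes without a symbol. Symbols were taken through the Entrez number in a RefSeq gene table of assembly GRCh38.p14 for 35665 probes and through an accession for 85. For 8204 probes the symbol of the file was kept, and 3270 had none. Probe positions are those of the file, whose build is not given; the starts of both CDKN1A probes (36646665 and 36762947 on chromosome 6) lie too far apart for 1 gene, so positions may mix builds and only that of an MDM2 probe is given.

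Groups were compared with lmFit and eBayes in limma (prior degrees of freedom 5.52) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 18 lists. With an estimated correlation, camera refers its statistic to the residual degrees of freedom, 2 here. That alternative therefore has little power whatever the correlation, and a list that fails it is not shown to be correlated. The fry test, which asks whether the genes of a list move 1 way on balance and compares them with no other genes, was an alternative. Some genes belong to more than 1 list: 20 were in 2. For a gene not detected on any array of 1 group, the fold is a bound: the mean of the other group against, per array, the higher of the lowest detected value and the gene's own. An exact permutation test of 2 against 2 cannot go below p = 0.333, so that test could not pass 0.05 for any gene. On simulated arrays with the gene means and spread of this comparison (13548 genes, 50 changed at each fold), the test recovered 10% of changes of 1.5-fold, 76% of 2-fold, 100% of 3-fold and 98% of 4-fold, with 6 false calls among 148. A simulated list of 60 genes shifted by -0.35 was called by camera, with a median of -0.32, and an unshifted list of 60 was not, with a median of -0.0099. The simulation changed far fewer genes than the 1990 called in the comparison, so the adjusted threshold was stricter and recovery may differ. Its genes were independent, so the simulated lists do not test the effect of correlation between genes or of differences shared by arrays.

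The design, the lists, the alternatives and the naming rule were fixed before the data were examined. The rule named MDM2 and CDKN1A, the 12 largest rises and falls among called genes whose knockdown arrays both lay on one side of both controls, up to 4 members of each list by p, up to 12 called p53 targets, and up to 3 genes whose called probes disagreed in sign. Some genes that the rule selected are not reported here. The alternatives were other background corrections, scaling to a common median, the authors' processed values, other filters, other probe choices, other variance models, the replicate number as a block, other thresholds and tests, and leaving out each array. A slide effect was not run, since no slide was given.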

Results

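Gene expression was measured on Illumina bead arrays in HCT116, a human colorectal carcinoma line. Cells treated with small interfering RNAs (siRNAs) against circ-MDM2, a circular RNA made from the MDM2 locus, were compared with cells that received a negative control siRNA. MDM2 encodes the main E3 ubiquitin ligase of p53, and the series asks what the circular RNA does to proliferation and to basal p53. Each group had 2 arrays, described as biological duplicates. Between 16227 and 17970 of 47224 probes were detected per array, the fewest on circ-MDM2 siRNA replicate 2. The median raw intensity ran from 73.3 to 79.6 and the highest from 6595.7 to 7019.5. The number of arrays limits the precision of every value below. Log2 fold changes are knockdown minus control, with the standard error (SE) of the limma fit.

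The signal of the MDM2 gene did not pass the test between the groups. The array carried 4 MDM2 probes, and 1 of them was detected, at raw intensities of 98.3 and 96.9 in the controls and 84.1 and 77.5 after knockdown. This probe (ILMN_1736829, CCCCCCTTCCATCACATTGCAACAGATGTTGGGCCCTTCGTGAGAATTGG) lies on chromosome 12 at 67519358 to 67519407, in coordinates whose build is not given in the sources used here. Its log2 fold change was -0.30 (SE 0.13, limma adjusted p = 0.167 over all probes), and 0.14 when arrays were scaled to a common median, or -0.09 relative to the median of all genes. Each MDM2 probe is placed on 50 adjoining bases, so none crosses the back-splice junction of the circular RNA, and these values do not check its silencing. Whether the detected probe lies in an exon that the circular RNA also holds was not examined, since probes could not be aligned. Its value was therefore not assigned to linear or circular RNA.

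The knockdown arrays differed widely from the controls. Of 13548 genes tested, 997 were higher and 993 lower after circ-MDM2 knockdown in limma at an adjusted p under 0.05, and 132 and 76 of them by at least 2-fold. In every called gene both knockdown arrays lay on one side of both controls, as they did in 60.4% of all genes, against 33.3% by chance. The balance of directions depended on the scaling: 50.1% of calls were higher after quantile normalisation and 82.1% (3604 higher, 784 lower) when arrays were scaled to a common median, which moved the median of all genes to 0.23. The number of calls also depended on which array was left out. The spread of a gene was then taken from the intact pair alone, and the knockdown pair differed more (SD of the difference 0.26, against 0.19 for controls). Without control siRNA replicate 1 the test called 1 gene higher and 0 lower, with 2500 genes at an unadjusted p under 0.05, and without control siRNA replicate 2 it called 20 and 12. Without circ-MDM2 siRNA replicate 1 it called 1571 and 1818. Of the 90 called genes that the naming rule selected, 1 (ANGPTL4) was still called without control siRNA replicate 1 and 18 without control siRNA replicate 2. The probe reported was still tested for 87 of them in each case, and all 87 kept their sign. Since both knockdown arrays already lay on one side of both controls, the sign could change only through the renewed normalisation.

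The largest rise was that of ANGPTL4, a secreted inhibitor of lipoprotein lipase, at a log2 fold change of 3.25 (SE 0.12, adjusted p = 0.000133), or 9.53-fold. Its normalised log2 signal went from 5.24 ± 0.10 to 8.49 ± 0.0032 (SD, n = 2). A second ANGPTL4 probe gave 0.29 (SE 0.15, adjusted p = 0.234). DDIT4, an inhibitor of mTORC1 induced by stress, rose by 1.91 (SE 0.12), the keratin gene KRT80 by 2.06 (SE 0.14), the inhibitory SMAD gene SMAD6 by 1.88 (SE 0.20, detected on 1 of 2 controls), the hyaluronan-binding CEMIP by 1.82 (SE 0.17) and the serine protease KLK7 by 1.74 (SE 0.15). CLDND2 rose by 1.86. Probes of short nuclear RNAs were also among the 12 largest rises. SNORD13 rose by 2.62 (SE 0.20), SCARNA16 by 1.99 and RN7SK, which sequesters the elongation factor P-TEFb, by 1.82. The others were LOC728285 (2.54) and LOC644350 (2.00), known here by locus number.

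The largest fall was that of MKNK2, a kinase of the translation factor eIF4E, whose log2 fold change was -2.42 (SE 0.13, adjusted p = 0.000616), or 5.36-fold lower; its other probe gave -0.43 (SE 0.12, adjusted p = 0.0554). The mitochondrial lipid kinase gene AGK followed at -2.35 (SE 0.17) and the mitochondrial citrate carrier SLC25A1 at -2.25 (SE 0.13). RPS6KB2, an S6 kinase, fell by 1.72, and its second probe also fell, by 0.80. RPS19BP1 (-1.93), CCDC167 (-1.88), MTLN (-1.78), ORMDL1 (-1.69) and CEP20 (-1.64) were also among the largest falls, with RPL26P30 (-1.70), a pseudogene whose probe may also bind related ribosomal protein messages and whose value is uncertain.

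**Figure D1:**
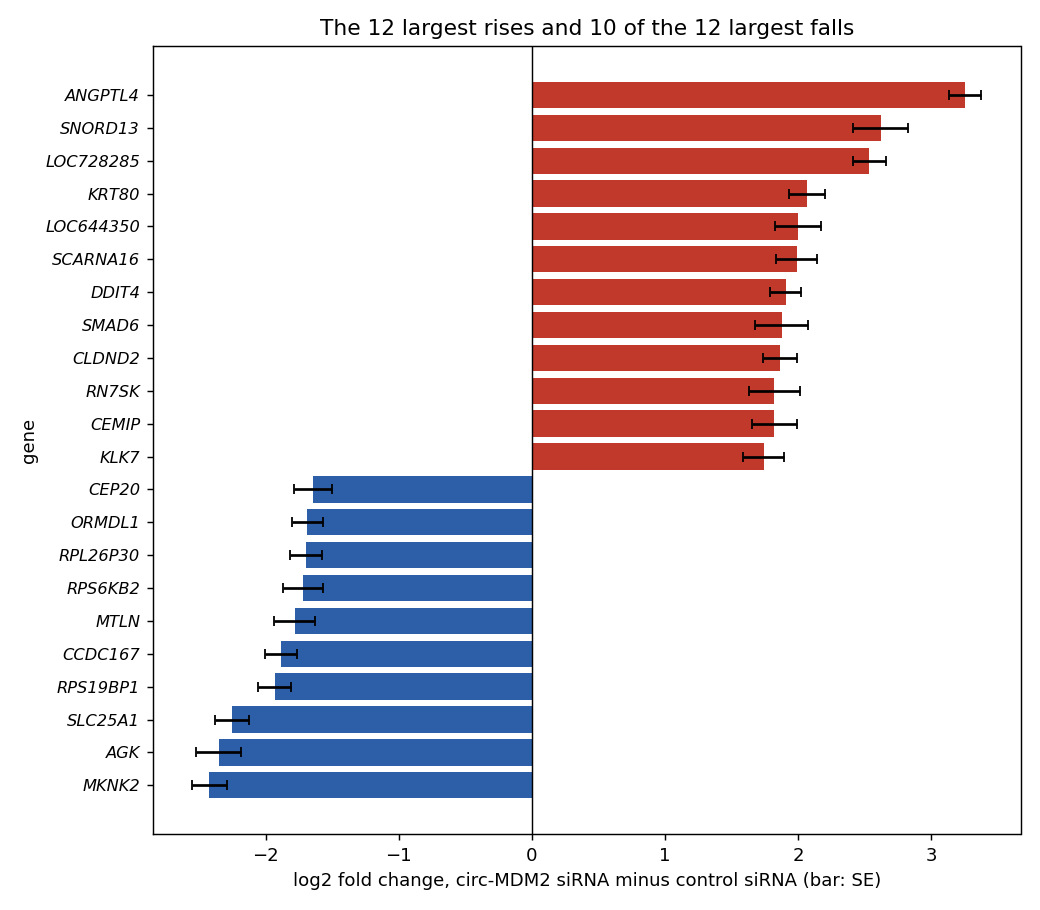
The 12 largest rises (red) and 10 of the 12 largest falls (blue) among called genes whose knockdown arrays both lay on one side of both controls. The horizontal axis is the log2 fold change (knockdown minus control), the vertical axis the gene, and error bars are the SE of the limma fit; ANGPTL4 rose the most (3.25) and MKNK2 fell the most (-2.42).

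Targets that p53 activates rose as a list under the preset correlation (median 0.11, camera adjusted p = 0.0114, but adjusted p = 0.336 with an estimated correlation). At a common median the list did not pass (0.37, or 0.14 above the median of all genes, adjusted p = 0.239). Without circ-MDM2 siRNA replicate 1 its median was 0.19. Of 71 measured members 8 rose and 1 fell, and the counts were also 8 and 1 when adjusted over the list alone. TP53INP1, a p53-induced promoter of autophagy and cell death, rose from 5.82 ± 0.07 to 6.81 ± 0.03 (SD, n = 2), a log2 fold change of 1.00 (SE 0.12, adjusted p = 0.00472), although its second probe gave 0.27 (adjusted p = 0.180). DRAM1, another autophagy gene, rose by 1.01 (SE 0.15), the mTORC1 inhibitor SESN1 by 0.91 (SE 0.12), the secreted stress cytokine GDF15 by 0.84 (SE 0.12) and the antiproliferative BTG2 by 0.77 (SE 0.12). BLOC1S2 rose by 0.66, NOTCH1 by 0.64 and the proapoptotic BAX by 0.50, with -0.13 (adjusted p = 0.746) on its other probe. TRAF4 fell by 0.61 and was not called at a common median (-0.30, or -0.53 relative to all genes, adjusted p = 0.130). CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 fold change of 0.45 (SE 0.13, adjusted p = 0.0525) from 11.35 ± 0.14 to 11.80 ± 0.02, just outside the threshold. At a common median it was called (0.80, or 0.57 above all genes, adjusted p = 0.0119), and its dimmer probe rose by 0.53 (SE 0.12, adjusted p = 0.0328 over all probes). Raw intensities overlapped between the groups. They were 2781.6 and 3448.3 in the controls against 3512.7 and 2865.9 after knockdown on the brighter probe. On the dimmer probe they were 84.6 and 88.4 against 91.6 and 81.5, so these rises rest on the scaling between arrays.

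**Figure D2:**
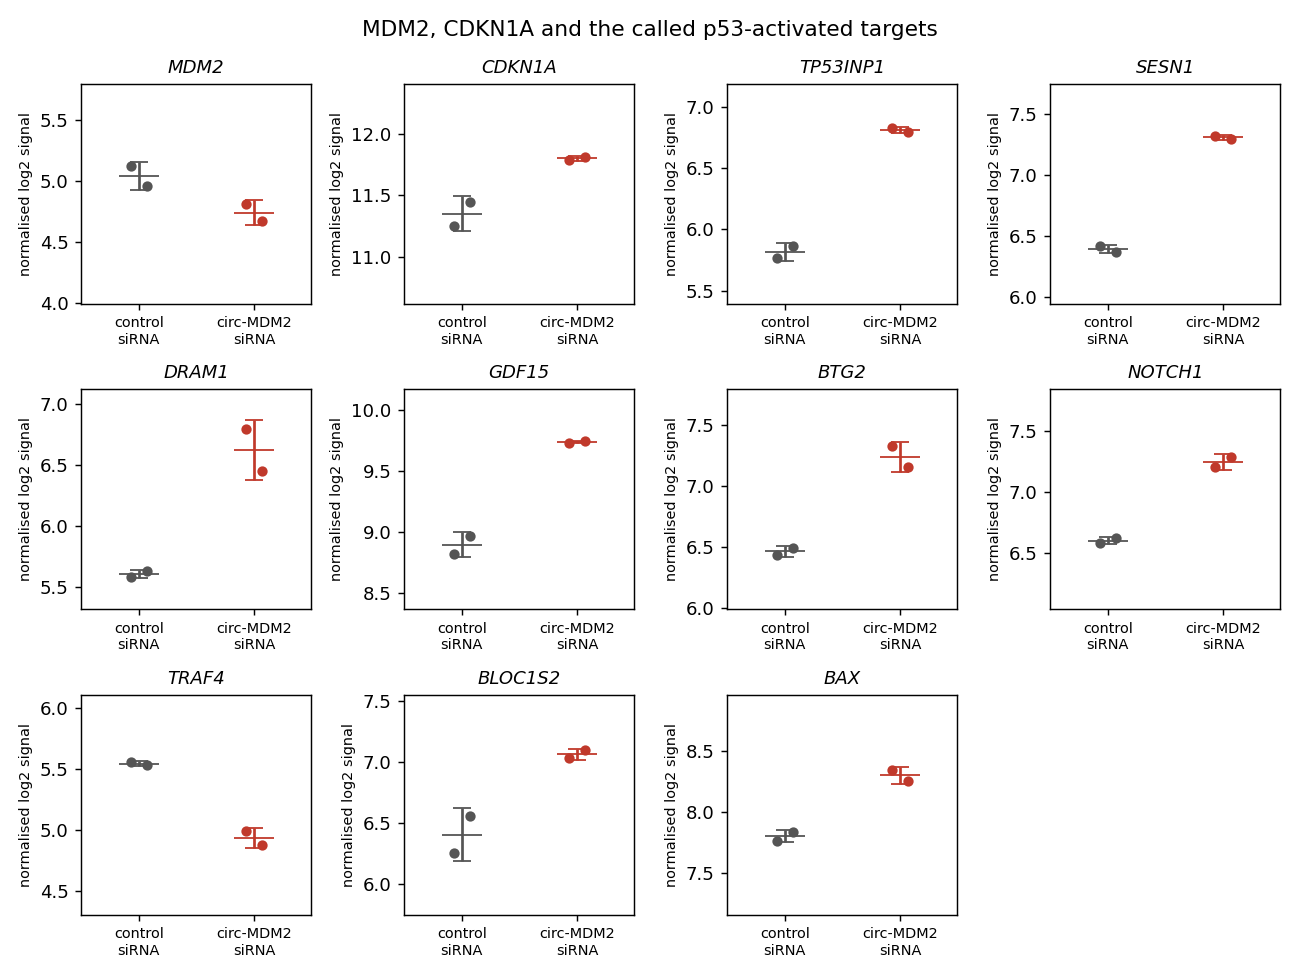
Normalised log2 signal of MDM2, CDKN1A and the 9 called p53-activated targets on each array (points), with the mean (line) and SD (bars) of the 2 control (grey) and the 2 knockdown (red) arrays. All panels span the same number of log2 units, and TRAF4 is the called target that was lower after knockdown.

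Genes of DNA replication and of mitosis fell under the preset correlation. The median log2 fold change was -0.39 for G1/S and -0.36 for G2/M (camera, adjusted p = 3.5e-10 and 1.58e-09), and with an estimated correlation each had an adjusted p = 0.285. The estimates were 0.023 for G1/S and 0.0045 for G2/M. The G2/M estimate lay below the preset 0.01, so its loss came from the 2 residual degrees of freedom of that alternative. Of 63 measured G1/S and DNA replication genes 18 fell and 1 rose, and 37 fell and 1 rose when adjusted over the list alone; 58 of the 63 values were below 0. Thymidine kinase TK1 fell by 0.89 (SE 0.12, adjusted p = 0.00615), the ribonucleotide reductase subunit RRM2 by 0.85 (SE 0.12), the origin recognition subunit ORC1 by 0.87 (SE 0.12) and cyclin E2 (CCNE2) by 0.90 (SE 0.14). The 1 member that rose, DUT, the enzyme that degrades dUTP, was named after its value was seen (0.52, SE 0.14). Of 73 measured G2/M genes 20 fell and 0 rose, with 33 and 0 when adjusted over the list alone, and 67 values were below 0. The spindle gene DLGAP5 fell by 0.73 (SE 0.13) and by 0.78 on its second probe, TROAP by 0.78 (SE 0.14), the cohesin protector SGO2 by 0.80 (SE 0.16) and the phosphatase CDC25B by 0.65 (SE 0.13). The lists lay at -0.55 and -0.59 relative to all genes at a common median.

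**Figure D3:**
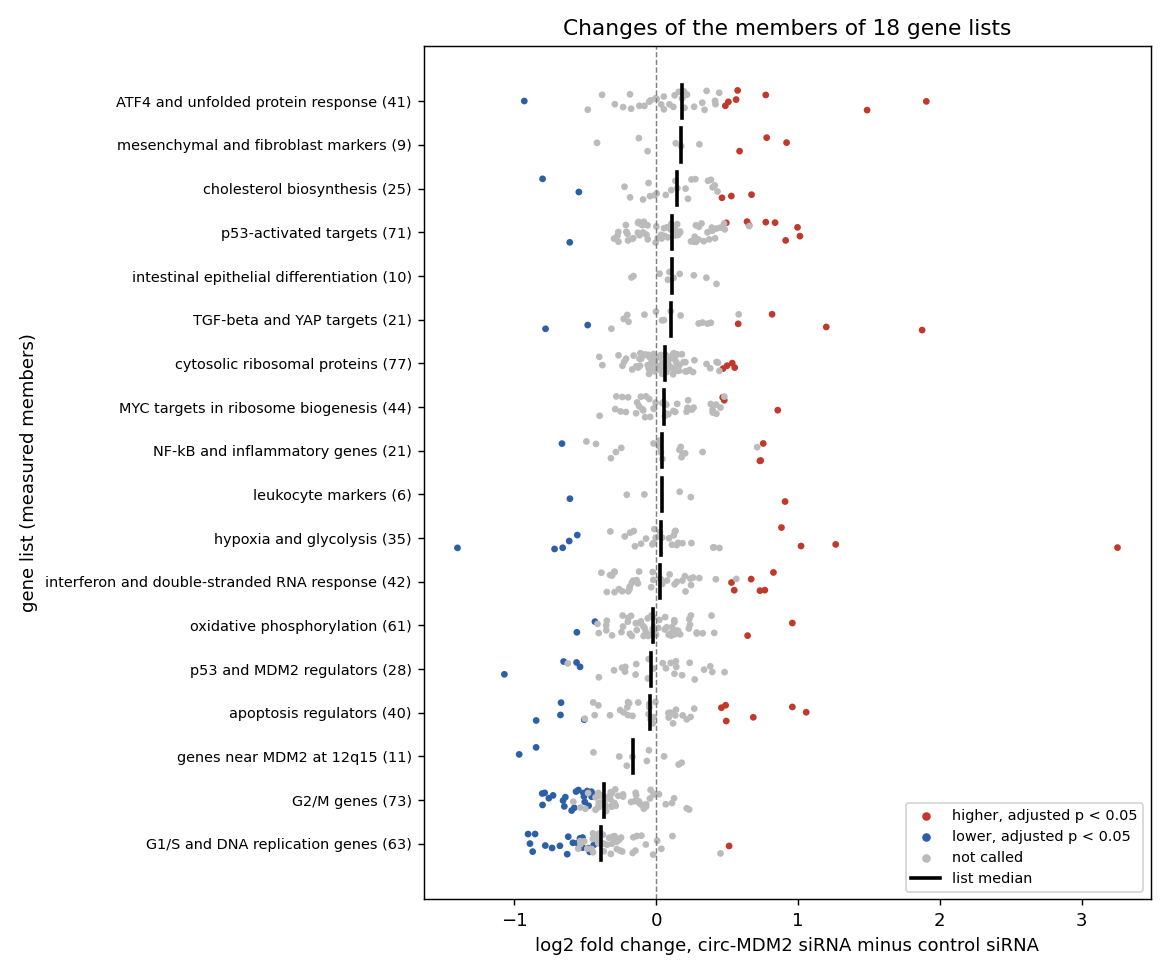
Log2 fold change (horizontal axis, knockdown minus control) of each measured member of the 18 gene lists (vertical axis, number measured in brackets), red or blue where called higher or lower and grey otherwise, with the list median as a black bar. The G1/S and G2/M lists have the lowest medians, at -0.39 and -0.36.

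Stress genes driven by ATF4 rose as a list under the preset correlation (median 0.18, camera adjusted p = 0.0159, but adjusted p = 0.395 with an estimated correlation). Of 41 measured members of the ATF4 and unfolded protein response list 7 rose and 1 fell (8 and 2 when adjusted over the list alone). DDIT4 is a member, the transcription factor gene ATF3 rose by 1.49 (SE 0.13, adjusted p = 0.00202) and the serine synthesis gene PSAT1 by 0.77 (SE 0.12), while PCK2, of mitochondrial gluconeogenesis, fell by 0.93 (SE 0.14). The list did not pass at a common median (adjusted p = 0.553, 0.0058 below the median of all genes), without control siRNA replicate 1 (median 0.12, adjusted p = 0.0929) or without circ-MDM2 siRNA replicate 1 (0.15, adjusted p = 0.0673). Nor did it pass with fry, a test of a list on its own (adjusted p = 0.0811).

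Hypoxia and glycolysis genes went both ways. Of 35 measured members 4 rose and 5 fell, with 5 and 5 when adjusted over the list alone (list median 0.04, camera adjusted p = 0.443, fry adjusted p = 0.0399, and 0.521 in camera with an estimated correlation). ANGPTL4, the glycolytic aldolase ALDOC (1.27, SE 0.14) and the vasodilator peptide gene ADM (1.02, SE 0.12) rose, and NDRG1 fell by 1.40 (SE 0.12). Of 21 TGF-beta and YAP targets 4 rose and 2 fell, or 6 and 2 over the list alone (median 0.10, adjusted p = 0.132). Without circ-MDM2 siRNA replicate 2 this list passed (0.29, adjusted p = 0.0296), without replicate 1 its median was 0.03, and with an estimated correlation it had an adjusted p = 0.395. SMAD6, SMAD7 (0.82, SE 0.12) and the receptor kinase gene AXL (1.20, SE 0.15) rose, and the transcriptional inhibitor gene ID3 fell by 0.78. Of 42 interferon and double-stranded RNA response genes 6 rose and 0 fell by both adjustments, with a median of 0.03 (adjusted p = 0.435). IFI6 rose by 0.83 (SE 0.13), OASL by 0.77 (SE 0.15), IFITM2 by 0.67 (SE 0.12) and IFITM3 by 0.55 (SE 0.12). Of 21 NF-kB and inflammatory genes 3 rose and 1 fell, or 4 and 3 over the list alone (median 0.04, adjusted p = 0.443), among them the chemokine gene CXCL8 (0.76, SE 0.12), the laminin chain LAMB3 (0.73, SE 0.12) and the NF-kB inhibitor NFKBIA (0.74, SE 0.14), while BCL3 fell by 0.66, a call lost at a common median (-0.38, or -0.62 relative to all genes, adjusted p = 0.152).

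Checkpoint kinase genes were among the regulators of p53 and MDM2 that fell. Of 28 measured members 4 fell and 0 rose by both adjustments (median -0.03, adjusted p = 0.712). CHEK2 fell by 1.07 (SE 0.14), the deacetylase gene SIRT1 by 0.65 (SE 0.15), CHEK1 by 0.54 (SE 0.12) and ATM by 0.56 (SE 0.14), of which ATM was not called at a common median (-0.27, or -0.50 relative to all genes, adjusted p = 0.162). Of 11 measured genes near MDM2 at 12q15, 2 fell and 0 rose (3 and 0 over the list alone): RAB3IP by 0.96 (SE 0.13), whose second probe gave -0.04, and the chromatin reader gene YEATS4 by 0.85 (SE 0.12). This list had a median of -0.17 (adjusted p = 0.132), or 0.11 above all genes at a common median. It passed with no filter (-0.10, adjusted p = 0.0164), had an adjusted p = 0.395 with an estimated correlation, and its median was -0.03 without control siRNA replicate 1 and -0.06 without control siRNA replicate 2. Of 40 apoptosis regulators 6 rose and 4 fell, or 6 and 6 over the list alone (median -0.04, adjusted p = 0.833). Cytochrome c (CYCS, 0.96, SE 0.12) and the BH3-only gene BIK (1.06, SE 0.15) rose, and BAD fell by 0.84 (SE 0.13). BAK1 was not detected after knockdown. It was at least 1.41-fold lower after quantile normalisation, a bound not met at a common median (-0.11, or -0.34 relative to all genes, adjusted p = 0.661).

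Metabolic and growth lists did not pass with the main settings. Of 25 cholesterol synthesis genes 3 rose, among them squalene epoxidase SQLE (0.53), and 2 fell, INSIG1 by 0.80 and MVD by 0.54, with the same counts over the list alone (median 0.15, adjusted p = 0.129). This list passed with no filter (0.18, adjusted p = 0.0144), had an adjusted p = 0.395 with an estimated correlation, and its median was 0.25 without circ-MDM2 siRNA replicate 1. Of 44 MYC targets in ribosome biogenesis 3 rose, CAD by 0.86, PES1 by 0.47 and IMP4 by 0.48, and 0 fell (1 and 0 over the list alone; median 0.06, adjusted p = 0.153). Of 77 cytosolic ribosomal protein genes 4 rose and 0 fell, led by RPL22 (0.55) and RPL7 (0.54), and none of either direction was called over the list alone (median 0.07, adjusted p = 0.132). The ribosomal protein list passed at a common median (0.54, or 0.31 above all genes, adjusted p = 1.46e-05), with no filter (0.07, adjusted p = 0.0457) and over all probes (0.11, adjusted p = 0.0109), and had an adjusted p = 0.443 with an estimated correlation. Of 61 oxidative phosphorylation genes 2 rose (CYCS and NDUFS7, 0.65) and 2 fell (UQCRC2 and UQCRC1, by 0.56 and 0.43), or 2 and 0 over the list alone (median -0.02, adjusted p = 1.000).

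Marker lists of cell types did not pass with the main settings. Of 30 intestinal epithelial differentiation genes 10 were measured, and 0 were called by either adjustment (median 0.11, adjusted p = 0.263); AXIN2 had a log2 fold change of 0.43 (SE 0.13, adjusted p = 0.0619) and CDH1 of 0.35 (SE 0.12, adjusted p = 0.0919). Of 26 mesenchymal and fibroblast markers 9 were measured, of which 3 rose and 0 fell (3 and 1 over the list alone; median 0.18, adjusted p = 0.132): the smooth muscle actin gene ACTA2 by 0.92 (SE 0.12), TAGLN by 0.78 (SE 0.14, with 0.05 on its other probe) and S100A4 by 0.59 (SE 0.13). This list passed at a common median (0.36 above all genes, adjusted p = 0.0499) and with the strict filter (0.59, adjusted p = 0.0119), and had an adjusted p = 0.395 with an estimated correlation. It also passed without circ-MDM2 siRNA replicate 2, where its median was 0.37. Without control siRNA replicate 1 its median was 0.10. Of 24 leukocyte markers 6 were measured (1 rose and 1 fell by both adjustments, median 0.04, adjusted p = 0.903). AIF1, not detected after knockdown, was at least 1.30-fold lower after quantile normalisation, but not at a common median (-0.02, or -0.25 relative to all genes, adjusted p = 0.929). CD68 rose by 0.91 (SE 0.18) on a dim probe while its other probe gave -0.01. CD68 was not called at a common median (0.32, or 0.09 relative to all genes, adjusted p = 0.189).

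Called probes of a gene rarely went in opposite directions. Of 3122 genes with at least 2 tested probes, 205 had at least 2 called probes, and 8 of these had calls of both signs. Genes with a called probe beside an uncalled one, such as ANGPTL4, BAX and CD68, are not in this count. POLR1D, a subunit of RNA polymerases I and III, fell by 0.51 (SE 0.12) on its brighter probe, a call lost at a common median (-0.32, or -0.55 relative to all genes, adjusted p = 0.104), and rose by 1.29 (SE 0.16) on the other. FKBP14 had -0.83 (SE 0.13) and 0.58 (SE 0.16), and CDAN1 had 0.79 (SE 0.20) and -0.77 (SE 0.13). A single fold change does not describe these genes.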

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

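The lists of small non-coding RNAs and histones and the values of reported probes were added after the data were seen; all other alternatives were planned. Counts of genes (997 higher, 993 lower) moved by over 1.5 times as follows. With no filter they were 560 and 578, since 33737 genes were tested. At an adjusted p under 0.1 they were 1590 and 1693, at 1.5-fold or more 661 and 582, and with an ordinary unmoderated test, which has 2 residual degrees of freedom per gene, 1 and 2. At a common median 3604 were higher. Leaving out 1 array each gave 1 to 1571 higher and 0 to 1818 lower, the lone array of a group being assumed to vary like the other group. The authors' processed values gave 1373 and 1405 and shared 1749 of the 1990 calls with direction. The replicate number as a block gave 927 and 899, and changed no call of the p53, G1/S or G2/M list. Deviations of same-numbered arrays correlated at -0.08, so the numbers were not taken to pair the arrays.

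The p53 list kept its direction and passed except at a common median (0.37, adjusted p = 0.239) and with an estimated correlation (0.11, adjusted p = 0.336). With 1 array left out its median ran from 0.13 to 0.19. With fry the p53, G1/S and G2/M lists passed (adjusted p = 0.0313, 0.0264 and 0.0264), and of the others hypoxia and glycolysis alone (0.0399). The G1/S (-0.39) and G2/M (-0.36) medians lost their calls with an estimated correlation alone (adjusted p = 0.285 each). Of the other 15 lists 1 passed (ATF4), against 2 at a common median, 4 with no filter, 2 with the strict filter, 2 over all probes, 0 with an estimated correlation and 0 to 3 when 1 array was left out. At a common median, where all genes shifted by 0.23, some lists that did not pass changed the sign of their median. They were oxidative phosphorylation (0.20), apoptosis regulators (0.0475), regulators of p53 and MDM2 (0.15) and genes near MDM2 (0.34). Relative to all genes the medians of these lists were -0.03, -0.19, -0.08 and 0.11 in the same order. The shift therefore does not account for the change of sign of the genes near MDM2. The p53 and MDM2 regulators were at 0.0477 with the strict filter and 0.0454 over all probes, leukocyte markers at -0.0320 over all probes. Leaving out 1 array gave -0.0105 to 0.0809 for the interferon list, -0.0469 to 0.0200 for oxidative phosphorylation, -0.0769 to 0.00096 for apoptosis regulators, -0.0736 to 0.0337 for the p53 and MDM2 regulators and -0.10 to 0.38 for leukocyte markers.

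Among genes, the MDM2 probe went to 0.14 at a common median, FRS2 to 0.34, KRT19 to 0.0088, SNAI2 to 0.17 and LYZ to 0.46, none of them called in either setting. CD68 was -0.0118 with the strict filter, the value of its other probe, and POLR1D 0.39 over the mean of its probes. Without 1 array CD68 ranged from -0.11 to 0.90 and FKBP14 from -0.95 to 0.71, because another probe became the brightest. On the probes reported, followed after this was seen, they ranged from 0.71 to 1.22 and from -0.95 to -0.76. Of 1159 values of the 90 called genes under alternatives 953 kept sign and call, 201 kept the sign alone (163 of them with 1 array left out) and 5 changed sign. Except where said, the cause of these changes was not tested. On the same probe, leaving out 1 array could hardly change a sign, as the groups were separated in every called gene. A slide effect was not run. Genes near background, such as MDM2, depend most on the scaling: the dimmest quintile of genes had a median of 0.63 at a common median and -0.02 after quantile normalisation.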

Other observations

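The gene classes, the genes named from them and the tests in this part were chosen after the results were seen, except that the removal of trends on signal and on GC content was laid down before its outcome was known (its repeat at a common median was not). Gene Ontology terms as the array annotation gives them were tested with camera, 765 terms of 10 to 500 genes. At an adjusted p under 0.05, 10 terms were lower and 1 higher. With an estimated correlation, on 2 residual degrees of freedom, 0 of them passed (camera adjusted p = 0.998 for each). The lower terms were those of mitosis (127 genes, median -0.23), cell division, cell cycle, kinetochores, centromeres, DNA replication and its initiation (15 genes, median -0.41), microtubule motors and movement, and the nucleoplasm. The higher term was epidermis development (30 genes, median 0.32, adjusted p = 0.00172), of which 13 rose and 1 fell. The laminin chain genes LAMB3 and LAMA3 rose by 0.73 (SE 0.12) and 0.56 (SE 0.15), with the hemidesmosome collagen COL17A1 (1.05, SE 0.12), the skin protease KLK7 (1.74), EMP1 (1.12, SE 0.12) and the epithelial transcription factor ELF3 (0.85, SE 0.14). KLK5 was not detected in either control and was at least 1.74-fold higher.

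Probes of small non-coding RNAs (small nucleolar, small nuclear, Y and similar RNAs) rose widely. Which form of these RNAs the probes read was not examined. Of 123 such genes measured, 59 rose and 1, RNY1 (-0.58), fell, with a median of 0.52. Of the 123, 84 were detected on all arrays. A dim gene could pass the filter through the knockdown arrays alone, so the count and the median may in part reflect the filter. SNORA73B rose by 1.53 (SE 0.14), the telomerase RNA TERC by 1.48 (SE 0.15), RNU4-2 by 1.44 (SE 0.23) and the RNase P RNA RPPH1 by 0.95 (SE 0.14). Of 29 replication-dependent histone genes, 19 of them detected on all arrays, 12 rose and 0 fell. H2BC5 was at 1.39 (SE 0.14) and H2AC18 at 0.91 (SE 0.12). The values argue against a trend of fold change on signal as the whole cause. Removing it left the small RNA median at 0.53 (bootstrap interval 0.38 to 0.62). At a common median, where the trend was strong, its removal took the median from 0.86 to 0.47. The bootstrap resampled genes with the arrays held fixed, so its intervals show the spread among genes and not between arrays. Removing a trend on probe GC content left 0.51 (0.39 to 0.62), or 0.64 (0.57 to 0.70) at a common median. A larger share of RNA without poly(A) tails in the labelled material stays open: histone messages, which mostly lack such tails, had a median of 0.27 (0.16 to 0.68), but that value had been seen beforehand, and a change made by the knockdown itself would look alike. Under other settings the histone median ran from 0.06 (no filter) to 0.75 (common median), and from 0.39 to 0.54 with 1 array left out. The small RNA median ran from 0.06 with no filter on dim probes to 0.86 at a common median, and was 0.19 in the authors' processed values.

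Many probes that share at least 15 bases with the Alu consensus in the direction of the transcript also rose. This class was not tested against other genes or under other settings. Of 126 such genes 65 rose and 0 fell, with a median of 0.62 (0.51 on circ-MDM2 siRNA replicate 1 and 0.77 on replicate 2). Of all 13548 genes 997 rose and 993 fell, with a median of -0.01. Of 17 genes whose probe matched the complement 0 were called, with a median of 0.09, but they were dim (mean log2 signal 4.68, against 7.11) and 5 were detected on all arrays, so few could have been called. In the probes of risen genes 24 of 4096 hexamers were overrepresented after Bonferroni adjustment, led by AGATCG, found in 30 where 6.40 were expected (adjusted p = 9.05e-10). Some of them overlap each other, such as AGATCG and GATCGC or GCACTC and CACTCC, so they are not separate findings. How many came from the Alu-like probes was not counted.

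The fall of the cell cycle lists was weighed against both trends. Over the 136 members of both lists the median was -0.38. It was -0.36 (bootstrap interval over genes -0.39 to -0.31) after removing the trend on signal. After removing that on GC content it was -0.36 (-0.38 to -0.31), so neither trend is the whole cause on these arrays. At a common median the value was -0.34 before and -0.38 (-0.40 to -0.32) after removing the trend on signal, and -0.55 (-0.61 to -0.50) after removing that on GC content. The knockdown of circ-MDM2 remains an untested explanation, because the arrays do not show how far it was silenced.

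For the 993 falls, off-target silencing through its seed, that of the siRNA, might explain a part. No hexamer was overrepresented in the probes of fallen genes (smallest Bonferroni-adjusted p = 1, for ACATTC, found in 23 where 10.4 were expected). The 24 hexamers found in risen genes overlap in part, so they do not show that this search could find a single seed. The probes cover 50 bases of each transcript and the siRNA sequence is not given in the sources used here, and the upper limit of the odds ratio reached 4.22, so this stays open.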
